A study of Homo sapiens with 6 samples.

How the data were processed

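RNA abundance was measured by sequencing in HCT116 cells, an epithelial line established from a human colorectal carcinoma. Cells were treated for 12 h, after overnight seeding, with tumonolide at 20 µM or with its vehicle, 0.5% DMSO. Tumonolide is a compound from a marine cyanobacterium, described in the series' title as a selective antagonist of TACR2, the receptor for the neuropeptide neurokinin A. Each condition had 3 libraries. The libraries are named here by the numbers in their labels, DMSO 1 to 3 and tumonolide 7 to 9, and no number is shared between the groups. Per the labels, RNA was isolated on Qiagen columns and 250 ng of total RNA entered a directional Illumina library kit from NEB. The labels do not say whether the 3 libraries of a group came from separate cultures, so the p-values measure the spread between these samples only, which may be technical.

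The deposited table of estimated counts has 56996 gene rows, with values that are not all whole (76.1% of values above 0 were exactly whole). Expected counts of this kind come from RSEM, which is named with Trimmomatic, STAR, SAMtools and DESeq2 in the submitters' processing notes, without versions or settings. The same notes give the genome build as GRCh38. The annotation release and the strand setting of the counting are not given in the sources used here. All 56996 gene identifiers were found in GENCODE release 29 on GRCh38, which supplied the coordinates, exon lengths, GC content and overlaps with exons of other genes. The overlaps were counted by position on either strand, so alone they do not show that reads of directional libraries were ambiguous. In the count table the tumonolide libraries carry the compound's laboratory code, and each column was matched to its sample by the number in its name.

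The authors also deposited a table comparing tumonolide with DMSO for 11911 protein-coding genes. Per the file headers it holds a log2 fold change, its standard error (SE), a p-value and a mean expression signal, the average normalized count, whose lowest value was 32.9. The deposited p-value followed the Benjamini-Hochberg adjusted p of fold change over SE (across genes, median ratio 1.035), not the unadjusted p (median ratio 2.07), and it was read as adjusted.

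Expected counts were rounded to whole numbers. Genes were kept by the edgeR function filterByExpr with its default minimums (10 counts, 15 in total), which left 14872 genes, and libraries were scaled by TMM. The groups were compared with the edgeR quasi-likelihood F-test (edgeR 4.0.16, R 4.3.3), fitted to the 6 libraries with no covariate. P-values were adjusted by the Benjamini-Hochberg method and a gene passed at an adjusted p under 0.05. "Rose" and "fell" are used of genes that passed. Levels are TMM-scaled CPM (counts set to a common scaled library total) as mean ± SD with n = 3 libraries per group, and fold changes are log2 of tumonolide over DMSO with their SE. A count of 0 was given a floor of 3 counts per library, which is 0.1 to 0.131 CPM and covers counting error only.

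Before the data were examined, 36 gene lists were fixed, holding 708 distinct genes of which 707 were matched. They covered the tachykinin system, Gq and calcium signalling, immediate early genes, ERK pathway output, NF-kB and inflammatory targets, p53 targets, DNA replication and G1/S, mitosis and G2/M, cholesterol synthesis and uptake, fatty acid synthesis, LXR targets, the unfolded protein response, ATF4 and amino acid response, NRF2 targets, heat shock, metallothioneins and metal response, hypoxia, glycolysis, the nuclear-encoded respiratory chain and mitochondrially encoded mRNAs. They also covered the xenobiotic response, cytosolic ribosomal proteins, ribosome biogenesis, type I interferon, TGF-beta targets, Wnt and beta-catenin targets, YAP and TEAD targets, SRF and actin cytoskeleton, tubulins, autophagy and lysosome, the proteasome, replication-dependent histones, intestinal differentiation, EMT and mesenchymal genes, apoptosis regulators and markers of other cell types. Lists with at least 5 tested members (35 of the 36) were compared with all other tested genes by camera (limma 3.58.1) with a preset inter-gene correlation of 0.01, and again with the correlation estimated from the residuals. The estimated form also takes its degrees of freedom from the residuals of the 6 libraries, which makes a call harder to reach. The fry test, which asks whether a list's own members move on balance in a single direction, was run beside it. Each set of list p-values was adjusted over the 35 lists. Member genes were also counted with their p-values adjusted over the list alone.

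The genes named were set by a rule fixed before the data were examined. It took the 6 tachykinin genes, and the 10 largest rises and 10 largest falls among passing genes with a mean of at least 1 CPM and no overlap between the groups. It also took the 5 rising and 5 falling genes with the smallest p under the same conditions, and up to 4 members of each list with the smallest p. Genes outside this rule are said to have been chosen after their values were seen.

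Alternatives fixed before the files were seen were DESeq2 size factors, library size alone, DESeq2 1.42.0, limma-voom, no low-count filter, a stricter filter (at least 1 CPM in 3 libraries), unrounded counts, leaving out each library in turn, an adjusted p under 0.01, and a test against a 1.5-fold change (glmTreat). Chosen after seeing the data were corrections for GC content and for exon length (a lowess curve of span 0.3 per library) and a fit without DMSO 1 and tumonolide 7, which lay apart on a principal component. On simulated counts for the 14872 genes of this comparison, the edgeR test recovered 43.3% of genes changed by 1.3-fold, 68.7% of those changed by 1.5-fold and 92.4% of those changed by 2-fold. Of its calls there, 91.3% were changed genes, and with no gene changed it made 1 call and camera called 0 lists. The changed genes all had a mean of at least 1 CPM. They numbered 67, 67 and 66 at 1.3-fold, 1.5-fold and 2-fold, far fewer than the 2374 genes that passed in the data. With fewer changed genes the Benjamini-Hochberg adjustment asks for a smaller p, so these shares need not hold for the real comparison. Each gene was drawn independently, so the 0 lists do not show how often camera calls lists falsely where genes vary together. In these libraries the estimated correlation within a list reached 0.969.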

Results

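Gene expression was profiled in 6 RNA sequencing libraries of HCT116 colorectal carcinoma cells, 3 from cells given tumonolide at 20 µM for 12 h and 3 from cells given the DMSO vehicle. The libraries held between 22943767 counts (tumonolide 8) and 29964675 counts (DMSO 1). Protein-coding genes took 97.8% to 98.2% of the counts, and the 10 most abundant genes took 5.30% to 6.45%. Libraries within a group differed by more than counting noise (chi-square per degree of freedom 6.07 to 21.49), so none was a copy of another, although separate preparations from a single culture would differ as well. The first principal component (33.65% of the variance) separated the groups, with DMSO libraries at -23.35 to -14.86 and tumonolide libraries at 10.83 to 23.52. The second (22.83%) set DMSO 1 (14.72) and tumonolide 7 (27.11) apart from the other libraries (-13.69 to -7.84). The share of the counts from mitochondrially encoded mRNAs, without mitochondrial rRNA, was also highest in these libraries within their groups. It fell in number order in both groups. It was 2.23%, 1.98% and 1.40% in DMSO 1, 2 and 3. In tumonolide 7, 8 and 9 it was 2.89%, 2.25% and 1.64%. Mitochondrial rRNA did not follow this order. Its share was 0.696%, 1.01% and 0.736% in DMSO 1, 2 and 3, and 0.814%, 0.969% and 0.791% in tumonolide 7, 8 and 9.

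The comparison asked which transcripts change in these cells when the compound is present. Genes of protein folding and export in the endoplasmic reticulum (ER) rose together in tumonolide-treated cells, with 19 of 20 tested members of the unfolded protein response list higher. Genes of the actin cytoskeleton (13 of 20) and of cholesterol synthesis and uptake (14 of 25) rose as well. The fry test did not call the cholesterol list (fry adjusted p = 0.104), and its count ran from 8 to 22 with 1 library left out. Genes of ribosome biogenesis (21 of 26) and of DNA replication (16 of 25) fell, mostly by less than 1.5-fold. In all, 2374 of 14872 tested genes passed (15.96%), of which 1131 rose and 1243 fell (edgeR quasi-likelihood F-test, Benjamini-Hochberg adjusted p under 0.05). Large changes were mainly rises, as 64 genes rose and 6 fell by 2-fold or more, 254 rose and 33 fell by 1.5-fold or more, and the median size among passing genes was 0.299 on the log2 scale. The groups did not overlap for 2348 of the passing genes and for 33.5% of all tested genes, where chance gives 10%. The count depended on the libraries, with 1292 genes without DMSO 2, 1487 without DMSO 3, 1371 without tumonolide 8, 1426 without tumonolide 9 and 3672 without both DMSO 1 and tumonolide 7. Of those called without DMSO 2, 1267 were among the 2374.

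**Figure D1:**
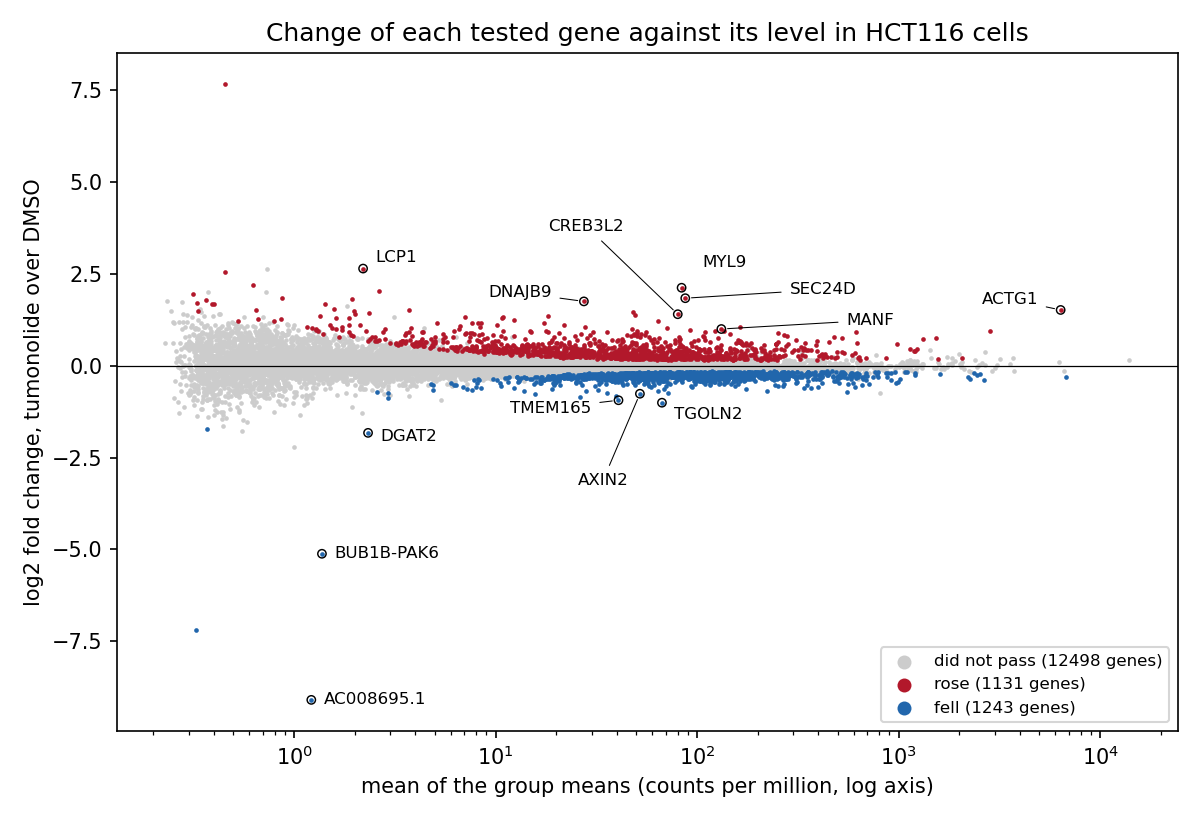
Each point is a tested gene, placed by the mean of the 2 group means in CPM (x axis, log scale) and its log2 fold change of tumonolide over DMSO (y axis). Red points are the 1131 genes that rose, blue points the 1243 that fell and grey points genes that did not pass, and the most extreme fitted values belong to genes with 0 counts in a group, for which the fitted change is no measure of size.

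The rises with the smallest p-values included several genes of the secretory pathway. SEC24D, which selects cargo for COPII vesicles leaving the ER (ENSG00000150961, chromosome 4, 118722823 to 118838683), rose from 38.1 ± 1.85 to 137 ± 7.23 CPM (SD, n = 3), a log2 fold change of 1.84 ± 0.060 (SE; edgeR adjusted p = 1.86e-08). CREB3L2, a transcription factor held in the ER membrane (ENSG00000182158, chromosome 7, 137874979 to 138002067), rose from 43.9 ± 1.08 to 116 ± 4.03 CPM (log2 fold change 1.41 ± 0.052). NUCB2, a calcium-binding protein of the secretory pathway (ENSG00000070081, chromosome 11, 17208153 to 17349980), rose from 25.6 ± 2.06 to 70.9 ± 1.86 CPM. MYL9, a regulatory light chain of myosin (ENSG00000101335, chromosome 20, 36541484 to 36551447), rose from 31.2 ± 2.12 to 136 ± 20.8 CPM, and HSPA13, a member of the HSP70 family (ENSG00000155304, chromosome 21, 14371115 to 14383484), rose from 62.1 ± 2.31 to 122 ± 2.70 CPM. Among genes with a mean of at least 1 CPM and no overlap between the groups, the largest rise belonged to LCP1, which encodes the actin-bundling protein L-plastin (ENSG00000136167, chromosome 13, 46125920 to 46211871), at 6.27-fold from a low level (0.602 ± 0.048 to 3.80 ± 0.114 CPM). BHLHA15, a transcription factor of secretory cells, rose 3.51-fold from 0.855 ± 0.121 CPM, and DNAJB9, an ER co-chaperone, rose 3.37-fold from 12.5 ± 3.36 CPM. Other large rises included those of ACTG1 (2.87-fold), C6orf223 (2.88-fold), CDRT4 and AL163636.2. CDRT4 has 73.7% of its exon bases within exons of other genes, on either strand. It had 0 counts in DMSO 3, and did not pass without DMSO 1, tumonolide 8 or tumonolide 9 (edgeR adjusted p = 0.0873, 0.113 and 0.0965). AL163636.2 lies wholly within exons of other genes and did not pass without DMSO 1, DMSO 3 or tumonolide 9 (edgeR adjusted p = 0.0636, 0.0824 and 0.136), with the log2 fold change going from 1.67 to 0.98 without tumonolide 9.

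TGOLN2, a protein of the trans-Golgi network (ENSG00000152291, chromosome 2, 85318020 to 85328425), fell from 89.3 ± 10.1 to 44.5 ± 2.15 CPM, a log2 fold change of -1.004 ± 0.077 (SE; edgeR adjusted p = 8.94e-06). TMEM165, a Golgi membrane protein needed for glycosylation (ENSG00000134851, chromosome 4, 55395957 to 55453397), fell from 53.5 ± 3.49 to 28.0 ± 0.831 CPM. DGAT2, an enzyme of triglyceride synthesis (ENSG00000062282, chromosome 11, 75759512 to 75801535), fell from 3.64 ± 0.524 to 1.01 ± 0.296 CPM. AXIN2, a feedback inhibitor of Wnt signalling (ENSG00000168646, chromosome 17, 65528563 to 65561647), fell from 65.4 ± 1.40 to 38.6 ± 0.869 CPM, and PFAS, an enzyme of purine synthesis (ENSG00000178921, chromosome 17, 8247618 to 8270491), from 89.9 ± 2.89 to 54.0 ± 2.93 CPM. TMEM238 (1.85-fold) and BCAM, a laminin-binding adhesion protein (1.69-fold), were also lower. At the same mean level, the largest apparent falls concern transcripts that lie mostly or wholly within exons of other genes and may not be separable from them. AC008695.1, whose exons lie wholly within those of other genes, went from 2.43 ± 0.818 CPM to 0 counts in the 3 tumonolide libraries, at least 21.8-fold lower against the floor of 3 counts per library. BUB1B-PAK6, a read-through of neighbouring genes with 97.2% of its exon bases within exons of other genes, went from 2.68 ± 1.601 to 0.071 ± 0.088 CPM. AC106886.5, with 92.4% within them, fell 1.77-fold. The fitted log2 fold change of BUB1B-PAK6, -5.12, moved to -4.51 without tumonolide 7 and to -6.82 without tumonolide 9.

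**Figure D2:**
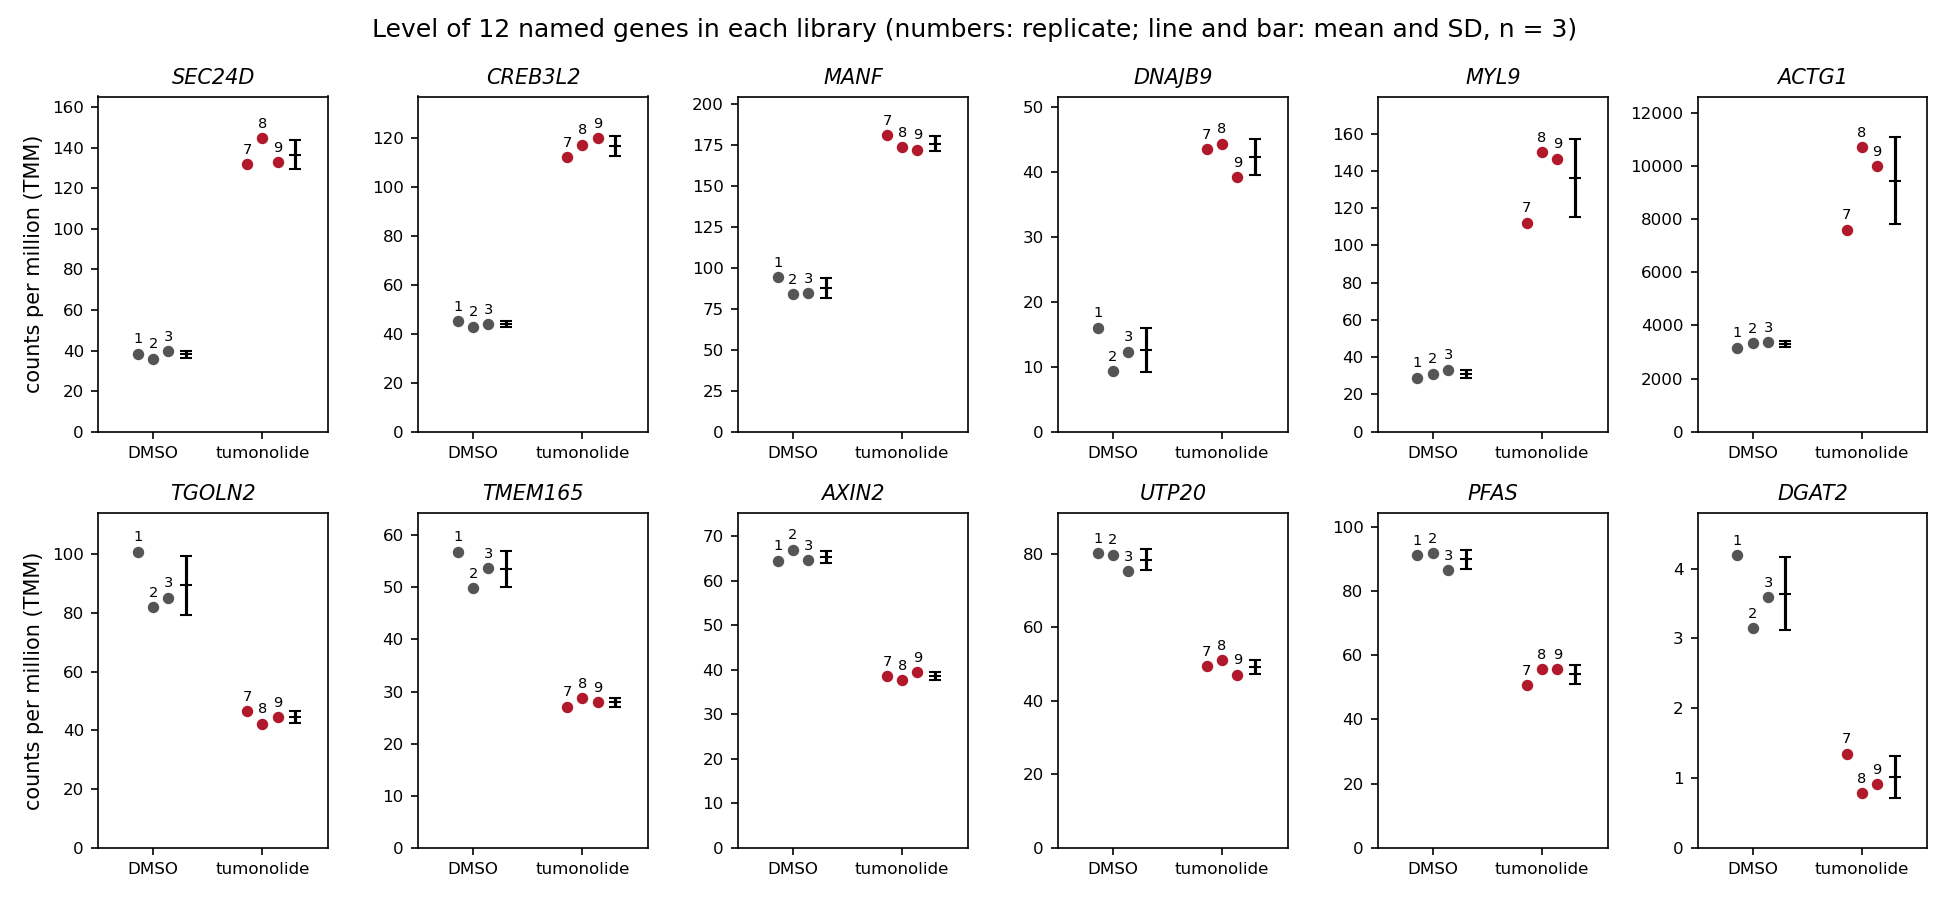
Each panel shows a gene's level in CPM (y axis, from 0) in the 3 DMSO libraries (grey) and the 3 tumonolide libraries (red), numbered by replicate, with the group mean and SD beside the points. In all 12 panels the groups do not overlap, as for SEC24D (38.1 ± 1.85 against 137 ± 7.23 CPM) and TGOLN2 (89.3 ± 10.1 against 44.5 ± 2.15 CPM). For most of these genes the lack of overlap was a condition of being named.

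Camera with the preset correlation called 19 of the 35 tested lists, 11 higher and 8 lower. The fry test called 10 of these and, besides them, TGF-beta targets, tubulins and markers of other cell types. It did not call cholesterol synthesis and uptake (fry adjusted p = 0.104), heat shock (0.208), mitosis and G2/M (0.271), fatty acid synthesis (0.171), NRF2 targets (0.06), the nuclear-encoded respiratory chain (0.167), mitochondrially encoded mRNAs (0.54), the xenobiotic response (0.06) or the proteasome (0.364). With an estimated correlation camera called 0, with 5 lists at an unadjusted p under 0.05 and a lowest adjusted p of 0.294. That loss need not be due to correlation, as this form also has few residual degrees of freedom. For Wnt targets the estimated correlation was -0.052, below the preset 0.01, yet the unadjusted camera p went from 0.00988 to 0.0531. For 10 of the 19 called lists, at least 1 of the 9 other groupings of the 6 libraries gave a smaller camera p than the real grouping. These were ERK pathway output, mitosis and G2/M, cholesterol synthesis and uptake, fatty acid synthesis, NRF2 targets, heat shock, the nuclear-encoded respiratory chain, mitochondrially encoded mRNAs, the xenobiotic response and the proteasome. The other groupings keep part of the tumonolide contrast, so they are not free of treatment. The p-values of lists in the text are camera p-values adjusted over the 35 lists, given with the preset and then with the estimated correlation.

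**Figure D3:**
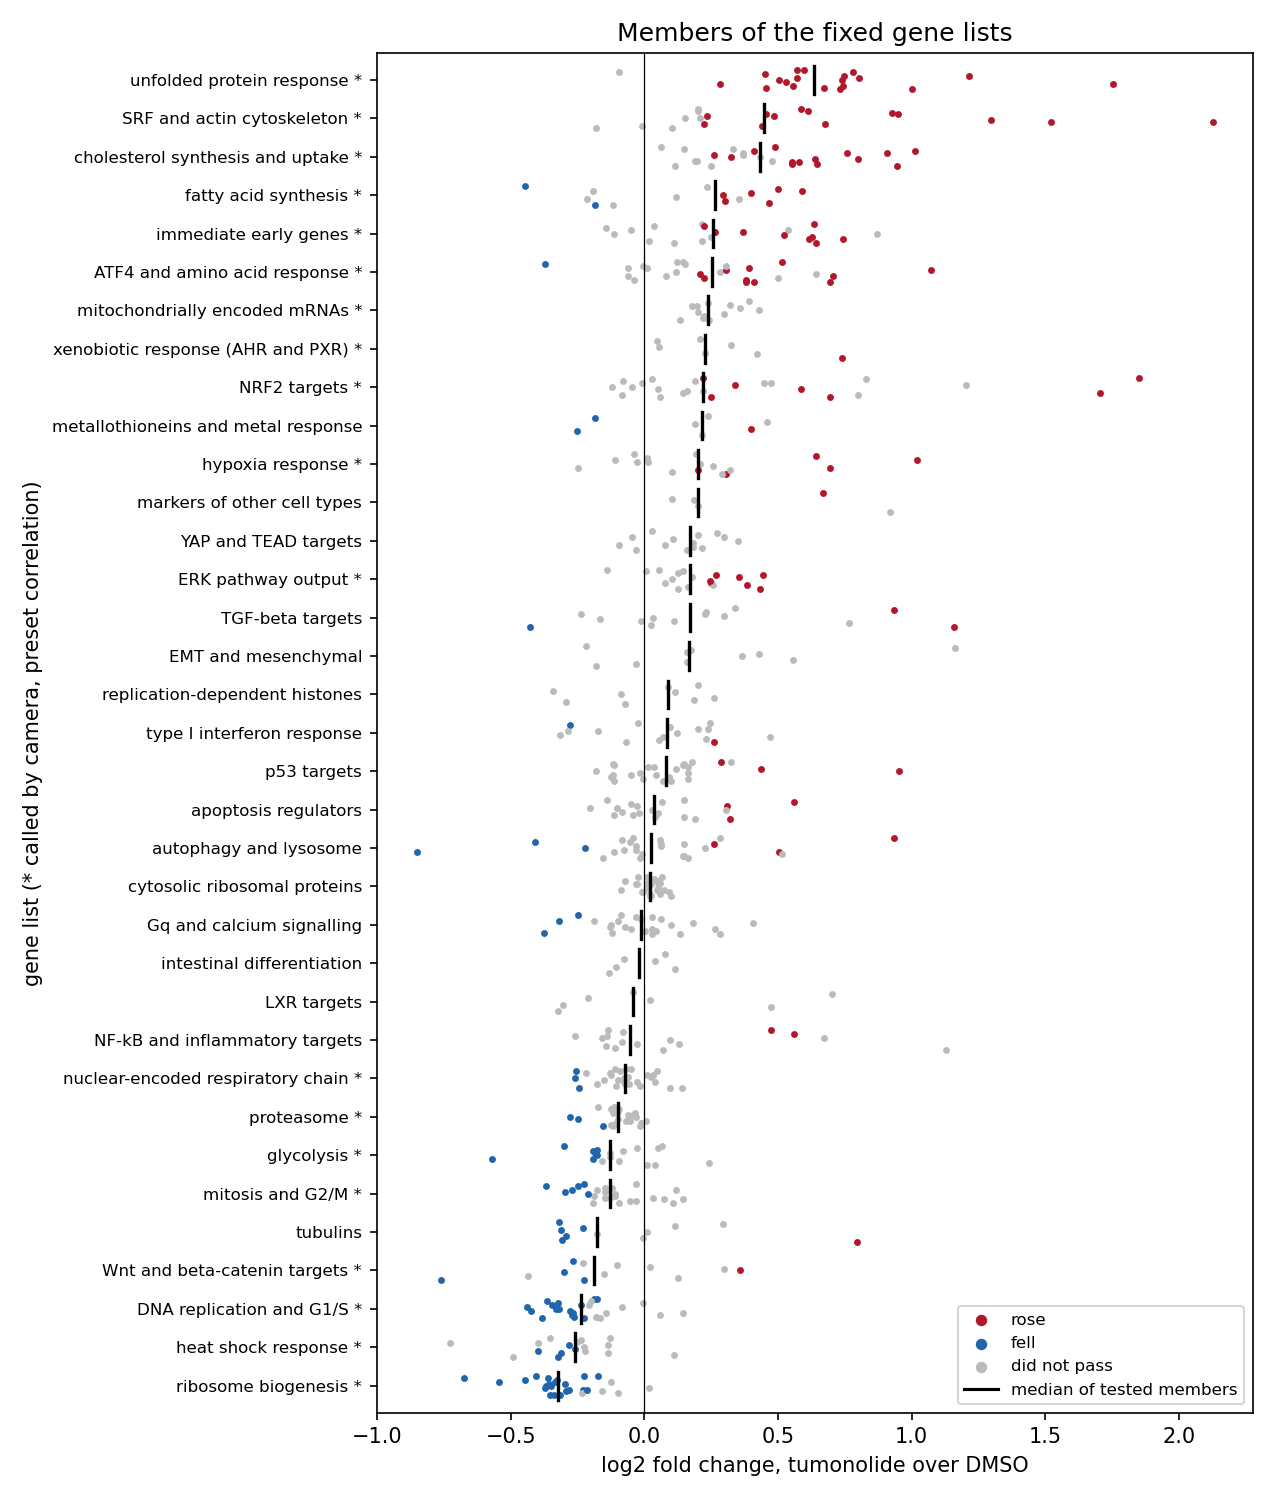
Each row is a fixed gene list, each point a tested member at its log2 fold change of tumonolide over DMSO (x axis), red where it rose, blue where it fell and grey where it did not pass, and each black line the median of the tested members. The medians run from -0.322 for ribosome biogenesis to 0.635 for the unfolded protein response, and stars mark the 19 lists called by camera with the preset correlation, which fall to 0 with an estimated correlation. The estimated form also has few residual degrees of freedom.

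In the unfolded protein response list, 19 of 20 members rose, also when adjusted over the list alone and without any single library. The median log2 fold change was 0.635 (adjusted p = 3.45e-23, and 0.294 with an estimated correlation). The ER chaperones and folding factors MANF (87.8 ± 5.91 to 176 ± 4.74 CPM), PDIA4 (351 ± 21.8 to 603 ± 18.4 CPM), HYOU1 (305 ± 7.90 to 485 ± 15.6 CPM) and HSP90B1 (1142 ± 51.4 to 1916 ± 90.8 CPM) rose by 1.59-fold to 2-fold. Among further members, chosen after their values were seen, HSPA5, which encodes the chaperone BiP, rose 1.66-fold and the transcription factor XBP1 rose 1.68-fold. The member that did not pass was ERN1, the stress sensor IRE1 (log2 fold change -0.10, edgeR adjusted p = 0.608). In the ATF4 and amino acid response list, 11 of 26 members rose and 1 fell (13 and 1 adjusted over the list alone), with a median of 0.253 (adjusted p = 1.07e-05, and 0.344 with an estimated correlation). ATF4 itself rose from 337 ± 11.3 to 448 ± 19.5 CPM, the stress gene DDIT4 rose 1.63-fold, the pseudokinase gene TRIB3 1.43-fold, and CHAC1, which degrades glutathione, 2.10-fold from 5.36 ± 0.440 CPM. The falling member, ATF5, was 1.29-fold lower (chosen after its value was seen). The ATF4 list's rising count was 5 without DMSO 2, 6 without tumonolide 9 and 7 without DMSO 1, DMSO 3 or tumonolide 8.

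In the SRF and actin cytoskeleton list, 13 of 20 members rose and 0 fell (15 and 1 adjusted over the list alone), with a median of 0.448 (adjusted p = 1.1e-12, and 0.294 with an estimated correlation). ACTG1, cytoplasmic gamma-actin, rose from 3289 ± 107 to 9444 ± 1632 CPM (log2 fold change 1.52 ± 0.100 SE), and ACTB, beta-actin, from 1948 ± 74.7 to 3758 ± 484 CPM. Both have many processed pseudogenes with which reads can be shared, so their separate levels are uncertain. The summed counts of 37 actin genes and pseudogenes went from 5241 ± 171 to 13210 ± 2112 CPM. ACTG1 and ACTB made up almost all of this sum in both groups, so few reads were assigned to the pseudogenes. TPM4, a tropomyosin, rose from 425 ± 12.98 to 809 ± 46.3 CPM. The mRNA of SRF itself did not pass (log2 fold change 0.10, edgeR adjusted p = 0.355; chosen after its value was seen). Leaving out DMSO 1 and tumonolide 7 gave 17 rising members and 1 falling. Of 20 immediate early genes, 9 rose and 0 fell (10 and 1 adjusted over the list alone; median 0.258, adjusted p = 3.77e-05, and 0.294 with an estimated correlation). They included the transcription factors KLF6 (73.5 ± 0.984 to 112 ± 3.85 CPM), JUN (23.0 ± 1.87 to 35.5 ± 1.67 CPM), KLF2 (1.55-fold) and ATF3 (1.44-fold). The number that rose was 5 without DMSO 2 or tumonolide 8, and 6 without DMSO 3 or tumonolide 9. Of 18 genes of ERK pathway output, 7 rose and 0 fell (8 and 0 adjusted over the list alone; median 0.171, adjusted p = 7.84e-05, and 0.352 with an estimated correlation). DUSP5, a phosphatase acting on ERK, rose from 74.2 ± 7.94 to 101 ± 6.92 CPM. DUSP4 rose 1.35-fold and IER3 1.3-fold, each with an edgeR adjusted p of 0.0549 without DMSO 2. The rising count of the ERK list was 1 without DMSO 2, 3 without tumonolide 8, 4 without DMSO 3 or tumonolide 9, and 11 without DMSO 1 and tumonolide 7.

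In the list of cholesterol synthesis and uptake, 14 of 25 members rose and 0 fell (22 and 0 adjusted over the list alone), with a median of 0.431 (adjusted p = 9.17e-11, and 0.371 with an estimated correlation). The enzymes HMGCS1 (83.4 ± 12.6 to 161 ± 45.3 CPM), MSMO1 (48.3 ± 5.78 to 81.6 ± 17.6 CPM), CYP51A1 (127 ± 8.97 to 197 ± 35.6 CPM) and SC5D (33.4 ± 3.83 to 49.9 ± 6.83 CPM) rose by 1.49-fold to 1.93-fold. For CYP51A1, 83.2% of the exon bases lie at positions that are also in exons of other genes, on either strand. The count was 8 without tumonolide 8, 9 without DMSO 1 or tumonolide 9, 22 without tumonolide 7 and 22 without both DMSO 1 and tumonolide 7. Of 14 fatty acid synthesis genes, 6 rose and 2 fell (8 and 4 adjusted over the list alone; median 0.264, adjusted p = 0.0357, and 0.674 with an estimated correlation). The desaturases FADS2 (1.41-fold) and FADS1 (1.38-fold), the elongase ELOVL6 (1.23-fold) and LPIN1, a phosphatidate phosphatase (1.5-fold), rose, while FASN, the fatty acid synthase, fell 1.36-fold and GPAM 1.14-fold (both chosen after their values were seen). FASN did not pass in 2 and GPAM in 4 of the 6 fits that left out 1 library (highest edgeR adjusted p = 0.106 without DMSO 3 and 0.129 without DMSO 2), and the falling count of the list was 0 without DMSO 2 and 1 without DMSO 3, tumonolide 8 or tumonolide 9. This list was not called without DMSO 1, tumonolide 8 or tumonolide 9 (adjusted p = 0.0975, 0.108 and 0.103). Of 7 LXR targets 0 passed by edgeR, DESeq2 or limma-voom, with 2 at an unadjusted p under 0.05 and a median of -0.0436 (camera adjusted p = 0.913; 1 higher and 1 lower adjusted over the list alone; 1 fell without tumonolide 7).

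Among stress and nutrient lists, 7 of 24 NRF2 targets rose and 0 fell (15 and 1 adjusted over the list alone; median 0.219, adjusted p = 0.000365, and 0.371 with an estimated correlation). They included the antioxidant enzymes TXNRD1 (538 ± 3.45 to 681 ± 47.7 CPM) and NQO1 (452 ± 15.1 to 537 ± 25.8 CPM). The NRF2 count was 2 without DMSO 2, 3 without tumonolide 8 and 11 without DMSO 1 and tumonolide 7. Of 17 hypoxia response genes, 5 rose and 0 fell (8 and 0 adjusted over the list alone; median 0.202, adjusted p = 0.00167, and 0.371 with an estimated correlation). NDRG1 rose from 90.3 ± 4.56 to 141 ± 5.89 CPM, INSIG2, an ER protein that holds back SREBP processing, from 14.5 ± 0.612 to 23.4 ± 1.07 CPM, and the secreted factor ANGPTL4 from 2.50 ± 0.677 to 5.07 ± 0.666 CPM. The hypoxia count was 3 without DMSO 2, tumonolide 8 or tumonolide 9, and 8 without both DMSO 1 and tumonolide 7. In the xenobiotic response list 1 of 7 members rose (2 adjusted over the list alone), namely CYP1A1, an enzyme induced through the aryl hydrocarbon receptor, at 1.67-fold from 3.57 ± 0.199 CPM (median 0.228, adjusted p = 0.0317, and 0.371 with an estimated correlation). That call was lost without DMSO 1, tumonolide 8 or tumonolide 9 (adjusted p = 0.0607, 0.0625 and 0.0882), and 3 members rose without tumonolide 7 and without both DMSO 1 and tumonolide 7. Of 7 metallothionein and metal response genes 1 rose and 2 fell (4 and 2 adjusted over the list alone; median 0.215, camera adjusted p = 0.259). These counts were 3 and 0 without DMSO 1, 0 and 0 without DMSO 2, 1 and 1 without DMSO 3, 2 and 2 without tumonolide 7, 2 and 0 without tumonolide 8, 1 and 0 without tumonolide 9, and 5 and 2 without both DMSO 1 and tumonolide 7.

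Of 26 ribosome biogenesis genes, 21 fell and 0 rose (24 and 0 adjusted over the list alone), with a median of -0.322 (adjusted p = 9.12e-17, and 0.294 with an estimated correlation). UTP20, a factor of small-subunit processing, fell from 78.5 ± 2.73 to 49.2 ± 1.98 CPM. POLR1A, the largest subunit of RNA polymerase I, fell from 183 ± 9.69 to 126 ± 4.16 CPM, MYBBP1A from 124 ± 1.44 to 90.8 ± 5.98 CPM, and HEATR1 from 187 ± 4.25 to 141 ± 7.60 CPM. With 1 library left out, 17 to 24 members fell. Of the 28 cytosolic ribosomal protein genes 0 passed by edgeR, DESeq2 or limma-voom, 0 had an unadjusted p under 0.05 by edgeR, 0 passed when adjusted over the list alone, and the median was 0.0219 (camera adjusted p = 0.453). Of 25 genes of DNA replication and G1/S, 16 fell and 0 rose (21 and 1 adjusted over the list alone; median -0.237, adjusted p = 9.17e-11, and 0.294 with an estimated correlation). The replication factor MCM10 fell from 114 ± 0.695 to 85.3 ± 4.49 CPM, the helicase subunit MCM4 from 455 ± 22.3 to 353 ± 5.94 CPM, the checkpoint mediator CLSPN 1.27-fold and UHRF1, which maintains DNA methylation, 1.26-fold. The replication count was 9 without DMSO 2 or tumonolide 9. Of 25 genes of mitosis and G2/M, 6 fell and 0 rose (6 and 0 adjusted over the list alone; median -0.13, adjusted p = 0.00167, and 0.674 with an estimated correlation). The mitotic kinase PLK1 fell from 219 ± 3.78 to 184 ± 6.31 CPM and CENPF, a kinetochore protein, from 348 ± 43.1 to 270 ± 13.2 CPM. The mitosis count was 2 without DMSO 1, tumonolide 8 or tumonolide 9, 4 without DMSO 2 or DMSO 3, and 13 without tumonolide 7 or without both DMSO 1 and tumonolide 7. Of 11 tubulin genes 5 fell and 1 rose (6 and 1 adjusted over the list alone; median -0.177, camera adjusted p = 0.0891, fry adjusted p = 0.0372). The falling count was 3 without DMSO 3, tumonolide 8 or tumonolide 9, and camera called the list without the low-count filter (adjusted p = 0.0393) and without both DMSO 1 and tumonolide 7 (0.0459). TUBB fell from 2451 ± 89.3 to 1974 ± 38.8 CPM and TUBA1A rose from 59.2 ± 12.9 to 103 ± 22.5 CPM, although alpha-tubulin paralogs share reads. Of 9 replication-dependent histone genes 0 passed by edgeR, DESeq2 or limma-voom, at an unadjusted p under 0.05 by edgeR or adjusted over the list alone (median 0.087, camera adjusted p = 0.79).

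Of 17 heat shock response genes, 5 fell and 0 rose (9 and 0 adjusted over the list alone; median -0.259, adjusted p = 0.000148, and 0.579 with an estimated correlation), and HSP90AB1 fell from 7483 ± 97.8 to 6025 ± 298 CPM. The heat shock count was 1 without tumonolide 8 or tumonolide 9, 2 without DMSO 1 or DMSO 2, 3 without DMSO 3, and 15 without tumonolide 7 or without both DMSO 1 and tumonolide 7. Of 25 proteasome genes 3 fell and 0 rose (2 and 0 adjusted over the list alone; median -0.1, adjusted p = 0.00234, and 0.674 with an estimated correlation), and PSMD1 was 1.21-fold lower. The proteasome list was not called without tumonolide 9 (adjusted p = 0.151), and 16 of its members fell without tumonolide 7, but 1 without any of the other 5 libraries. Of 18 glycolysis genes 7 fell and 0 rose (9 and 0 adjusted over the list alone; median -0.128, adjusted p = 0.0039, and 0.358 with an estimated correlation). Hexokinase HK2 fell from 70.7 ± 4.95 to 47.6 ± 2.80 CPM and GPI, glucose-6-phosphate isomerase, from 553 ± 40.8 to 449 ± 19.7 CPM. The glycolysis count was 2 without DMSO 2 or tumonolide 9, and 3 without DMSO 1, DMSO 3 or tumonolide 8. Of 29 nuclear-encoded respiratory chain genes 3 fell and 0 rose (3 and 0 adjusted over the list alone; median -0.0725, adjusted p = 0.00829, and 0.674 with an estimated correlation), among them CYC1, a subunit of complex III (1.20-fold). That list was not called without DMSO 2 (adjusted p = 0.0525) or tumonolide 9 (0.0842). Of its members, 7 fell without tumonolide 7 and 10 without both DMSO 1 and tumonolide 7. Of the 13 mitochondrially encoded mRNAs 0 passed by edgeR, DESeq2 or limma-voom, 1 had an unadjusted p under 0.05 by edgeR and 0 passed when adjusted over the list alone. Their median was 0.239 (adjusted p = 0.0391, and 0.687 with an estimated correlation), and -0.0132 without tumonolide 7, which had the highest share of these mRNAs (adjusted p = 0.644). The call was lost as well without DMSO 3 (adjusted p = 0.587) or tumonolide 8 (0.0501) and after the GC correction (median 0.223, adjusted p = 0.0532). Of these mRNAs 3 rose without tumonolide 9, 1 without DMSO 1 and 2 without both DMSO 1 and tumonolide 7.

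Of 12 Wnt and beta-catenin targets, 4 fell and 1 rose (6 and 1 adjusted over the list alone; median -0.189, adjusted p = 0.0216, and 0.31 with an estimated correlation). Besides AXIN2, the adhesion receptor CD44 fell from 461 ± 8.46 to 375 ± 11.4 CPM, and the rising member was DKK1, a secreted Wnt inhibitor (1.28-fold; chosen after its value was seen), which did not pass in 5 of the 6 fits that left out 1 library (highest edgeR adjusted p = 0.188, without DMSO 2). Without DMSO 3, 2 of the Wnt targets fell. This list was not called without both DMSO 1 and tumonolide 7 (adjusted p = 0.0572). Among lists that camera did not call, 2 of 14 TGF-beta targets rose and 1 fell (3 and 1 adjusted over the list alone; median 0.17, camera adjusted p = 0.135, fry adjusted p = 0.0117). Without tumonolide 7, 4 of them rose, without DMSO 1, 2 fell, and without DMSO 2 or tumonolide 9, 0 fell. LTBP2 rose (1.90 ± 0.120 to 3.62 ± 0.546 CPM).

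Of 26 p53 targets, 3 rose and 0 fell (3 and 0 adjusted over the list alone; median 0.082, camera adjusted p = 0.0784), and the list was called without DMSO 1, tumonolide 8 or tumonolide 9 (adjusted p = 0.00289, 0.0133 and 0.0425), with 5 members rising without DMSO 1 and 1 falling without tumonolide 7. It was also called without the low-count filter (adjusted p = 0.0356) and without both DMSO 1 and tumonolide 7 (0.0459), where 6 rose and 2 fell. GDF15, a secreted stress cytokine, rose from 92.7 ± 13.8 to 179 ± 14.0 CPM, PMAIP1, the pro-apoptotic protein NOXA, from 43.6 ± 1.301 to 59.0 ± 3.82 CPM, and CCNG1 1.22-fold. Of 20 apoptosis regulators, 3 rose and 0 fell (3 and 1 adjusted over the list alone; median 0.0346, camera adjusted p = 0.315), among them the pro-apoptotic BIK (9.81 ± 0.155 to 14.5 ± 0.511 CPM) and the inhibitor of apoptosis XIAP (62.7 ± 3.49 to 78.2 ± 2.94 CPM). Without DMSO 2 or DMSO 3, 2 of them rose, and without tumonolide 7, 1 fell. Of 26 autophagy and lysosome genes, 3 rose and 3 fell (6 and 4 adjusted over the list alone; median 0.0242, camera adjusted p = 0.467). The autophagy gene WIPI1 rose from 12.1 ± 0.642 to 23.3 ± 1.55 CPM and GABARAPL1 1.42-fold, while the lysosomal gene CTSA fell 1.33-fold. Without tumonolide 7, 5 members of this list rose and 4 fell. Of 16 NF-kB and inflammatory targets, 2 rose and 0 fell (2 and 0 adjusted over the list alone; median -0.0539 and mean 0.124, camera adjusted p = 0.719), with the cytokine LIF at 1.39-fold. The NF-kB list had 1 rising and 0 falling members without DMSO 2, DMSO 3, tumonolide 8 or tumonolide 9, and 2 of each without tumonolide 7. Of 16 type I interferon response genes, 1 rose and 1 fell (1 and 1 adjusted over the list alone; median 0.0831, camera adjusted p = 0.607), and the falling member, OAS3, was 1.21-fold lower, while 0 rose without DMSO 2, DMSO 3 or tumonolide 8. Of 14 YAP and TEAD targets, 10 EMT and mesenchymal genes and 6 intestinal differentiation genes, 0 passed by edgeR over all genes or adjusted over the list alone, with 2, 2 and 1 at an unadjusted p under 0.05. DESeq2 called 0, 0 and 1 of them, and limma-voom 0 of each. Without tumonolide 7, 1 EMT and 1 intestinal member rose. Their medians were 0.171, 0.168 and -0.0185 (camera adjusted p = 0.151, 0.348 and 0.852), and the YAP and TEAD list was called without DMSO 1 (adjusted p = 0.00787), where 3 members rose, and without both DMSO 1 and tumonolide 7 (0.0162), where 5 rose. Of the markers of other cell types, 5 were abundant enough to test and 1 rose (1 adjusted over the list alone; median 0.2, camera adjusted p = 0.135, fry adjusted p = 0.026). That member, the muscle intermediate filament DES, was at 1.80 ± 0.268 CPM in DMSO and 2.85 ± 0.100 CPM in tumonolide and did not pass when any of the 6 libraries was left out (edgeR adjusted p = 0.0653 to 0.155).

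The tachykinin receptors and ligands were near or at 0 counts in these cells. TACR2, the receptor named in the series' title (ENSG00000075073, chromosome 10, 69403903 to 69416867), had 5, 0 and 0 counts in DMSO 1, 2 and 3 and 3, 0 and 10 counts in tumonolide 7, 8 and 9, which is at most 0.344 CPM. TACR1 had 2 counts in each of tumonolide 7 and 8 and 0 in the other libraries. TACR3 had 7 counts in DMSO 1, 1 in tumonolide 9 and 0 elsewhere. The ligand gene TAC4 had 2 counts, all in tumonolide 9, and TAC1 and TAC3 had 0 counts in the 6 libraries, which allows up to 0.1 to 0.131 CPM per library. All 6 genes lay below the low-count filter. Without the filter 0 passed by edgeR (unadjusted p 0.0989 to 0.242), 0 had an unadjusted p under 0.05, and DESeq2 gave no adjusted p (unadjusted p 0.31 to 0.652), so a change in TACR2 mRNA was not detectable at this depth. Of 25 genes of Gq and calcium signalling, the pathway that TACR2 couples to, 3 fell and 0 rose (2 and 0 adjusted over the list alone; median -0.013, camera adjusted p = 0.567). ATP2B4, a plasma membrane calcium pump, fell from 94.9 ± 3.40 to 76.1 ± 8.91 CPM. ITPR1, an ER calcium channel (1.3-fold), did not pass without DMSO 1, DMSO 2 or tumonolide 9 (edgeR adjusted p = 0.0714, 0.0601 and 0.0932), nor did STIM1, an ER calcium sensor (1.19-fold), without DMSO 1, DMSO 3, tumonolide 8 or tumonolide 9 (0.143, 0.0935, 0.132 and 0.167). The falling count of this list was 1 without DMSO 1 or tumonolide 9 and 5 without tumonolide 7, where 2 rose, while 1 rose without DMSO 1.

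The authors' deposited table gave 1971 of its 11911 protein-coding genes past 0.05, of which 912 were higher and 1059 lower with tumonolide. Among the same genes the edgeR test called 2314. Both called 1672 genes, all with the same sign, while edgeR alone called 642 and the authors' deposited table alone 299. Across genes, which are not independent replicates, the fold changes had a Pearson correlation of 0.88 and a Spearman correlation of 0.886, and 88.5% had the same sign. Of the named genes that passed by edgeR, 112 are in the authors' deposited table, all with the same sign there and 102 past 0.05. Among the exceptions, the authors' deposited table gives CDRT4 a p of 0.433, AL163636.2 a p of 0.433 and BCAM a log2 fold change of -0.42 with a p of 0.131. Sizes also differed for some genes that passed in both. The log2 fold change of DGAT2 was -1.825 by edgeR and -1.012 in the authors' deposited table, and that of LTBP2 was 0.933 and 1.725.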

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

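The GC and length corrections and the fit without DMSO 1 and tumonolide 7 were chosen after the data were seen. The labels give no pairing between the groups, and no paired or blocked fit was run. Against 2374 genes (1131 rose, 1243 fell), rescaling gave 2358 (DESeq2 size factors) and 2342 (library size alone), DESeq2 2359, limma-voom 2305, no filter 2985, a stricter filter 2474 and unrounded counts 2370. Leaving out each library gave 1292 to 2810 genes, 639 to 1255 of them higher and 644 to 1555 lower, with fewer samples and so fewer degrees of freedom. Fewer degrees of freedom do not account for the rise to 2810 genes without tumonolide 7. An adjusted p under 0.01 left 1086 genes (563 rose, 523 fell) and 885 genes shared with the authors' deposited table in place of 1672. Tested against 1.5-fold, 48 passed (41 rose, 7 fell). The GC correction gave 2297, the length correction 2444 and leaving out DMSO 1 and tumonolide 7 gave 3672 genes (1695 rose, 1977 fell). The list count was 19 under both scalings and 0 with an estimated correlation, where other settings gave 13 (fry) to 21. Of 115 named genes that passed, 84 passed without each library in turn, and 0 changed sign under either scaling.

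Lists that were not called changed sign in camera where their median is near 0, and the cause was not tested. With each library left out, the median ran from -0.0756 to 0.0123 for LXR targets, from -0.0193 to 0.0546 for ribosomal proteins, from -0.0443 to 0.0568 for autophagy and lysosome, and from 0.00477 to 0.127 for histones, which stood at -0.0768 without both DMSO 1 and tumonolide 7. HIST1H2BD, which did not pass, ran from -0.03575 without tumonolide 9 to 0.3259 without DMSO 3. TACR2 lay below the low-count filter and did not pass without it (edgeR adjusted p = 0.576). In the simulation 43.3% of changes of 1.3-fold were recovered, so small changes can be missed. That share came from far fewer changed genes than passed here and need not hold for these libraries.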

Other observations

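Besides the fixed lists, genes were grouped into families. Some families of translocation into the ER or of transport between the ER and the Golgi held many rising members. Those of the nuclear pore and nuclear export held many falling members. The family tests and genes here, and below the tests of actin reads, the authors' deposited table, ERK output and the gene count of other groupings, were chosen after results were seen, while those of GC content and length, also added after the data were seen, and of the list count were set before their own values were known. Tested genes were grouped into 395 families by the letters that open their symbols, and camera with the preset correlation called 52 of them, 20 higher and 32 lower, although the lowest adjusted p with an estimated correlation was 0.614. In the SEC family, which holds coat and translocon proteins, 15 of 25 members rose and 0 fell (median log2 fold change 0.241, adjusted p = 9.19e-08), among them SEC61A1, the translocon channel (391 ± 30.2 to 658.5 ± 28.3 CPM), and SEC11C, a signal peptidase subunit (34.3 ± 2.38 to 60.1 ± 2.34 CPM). Grouped by symbol alone, it also holds SEC14L genes and SEC61B, a member of the unfolded protein response list. In the TMED family of cargo receptors 6 of 10 rose (adjusted p = 8.75e-05), including TMED10 (236 ± 3.21 to 385 ± 4.35 CPM), and in the YIPF family of Golgi membrane proteins 4 of 6 rose. Other families of this transport were not called, as TRAPPC (1 of 15 rose and 1 fell, adjusted p = 0.98), COG (2 of 8 rose and 1 fell, 0.72) and GOLGA (4 of 16 rose and 0 fell, 0.0969). Nor did camera call the vesicle families ARF (2 of 5 rose and 0 fell, 0.103), STX (3 of 14 and 0, 0.0535), RAB (8 of 61 and 0, 0.0905) or VAMP (1 of 6 and 0, 0.361). Single vesicle genes that rose included ARF4, of the uncalled ARF family (135 ± 4.24 to 201.5 ± 2.44 CPM), COPB2 (207 ± 4.17 to 284 ± 2.56 CPM), KDELR3 (21.2 ± 1.43 to 35.8 ± 3.27 CPM), USO1 (173 ± 10.8 to 254 ± 4.53 CPM) and BET1 (14.4 ± 1.23 to 26.8 ± 0.412 CPM). Each of these 5 passed without any single library (edgeR). GBF1, which activates ARF proteins at the Golgi, did not pass (log2 fold change -0.17, edgeR adjusted p = 0.0829).

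Of 21 NUP genes, which encode nuclear pore proteins, 14 fell and 0 rose (median -0.23, adjusted p = 1.23e-07), with NUP188 from 315 ± 5.73 to 224 ± 6.26 CPM. All 5 tested XPO exportin genes fell (adjusted p = 0.00233), as XPO1 did from 480 ± 19.6 to 404 ± 7.91 CPM. Of 49 MRPL genes, which encode proteins of the mitochondrial ribosome's large subunit, 15 fell and 0 rose (median -0.134, adjusted p = 1.23e-07), including MRPL12 (182 ± 8.97 to 144 ± 6.05 CPM), while of 29 MRPS genes, of its small subunit, 4 fell and 1 rose (adjusted p = 0.000639). PRPF8, a core splicing factor, fell with a log2 fold change of -0.59 (edgeR adjusted p = 3.58e-05), and 6 of 13 PRPF genes fell.

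Across 12200 genes with a log2 CPM over 1, fold change fell with GC content (Spearman correlation -0.163, and 0.003 after correction) and was nearly flat against exon length (Spearman correlation -0.011). After the GC correction the unfolded protein response median was 0.658 and that of ribosome biogenesis -0.292, and after the length correction they were 0.633 and -0.307, with both lists still called by camera. These values argue against a GC or length trend as the whole cause of either change. No DMSO percentage is given for the tumonolide libraries, so an effect of the vehicle may be part of the contrast. A transcriptional response of the cells to tumonolide may account for both changes, which remains a hypothesis found and examined on the same data. Measuring BiP protein and new rRNA at several doses and times in separate cultures would test it.

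The rise of the SRF and actin list could come from reads moved between actin paralogs and pseudogenes, but the summed actin counts rose by 1.33 on the log2 scale (lowest tumonolide library 10810 CPM, highest DMSO library 5403 CPM). That sum is almost wholly ACTG1 and ACTB, whose rise was already known. Of the 17 members other than actins 11 rose and 0 fell, and after the GC correction the list's median was 0.479. These values argue against both explanations for the list as a whole. For a single paralog the reads stay uncertain. ACTG2, the smooth muscle gamma-actin, had 0 counts in the 3 DMSO libraries and 0.906 ± 0.124 CPM in tumonolide, beside an ACTG1 level of 9444 CPM.

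The authors' deposited fold changes differ from a DESeq2 refit of the deposited counts by over 0.5 in 116 of 11911 genes, 57 of them with opposite signs, none of which is past 0.05 in both. A library left out by the authors does not explain this, as refits without 1 library correlated with the deposited values at most at 0.8577, against 0.8797 with all 6. Genes with 1 annotated transcript differed little (95th percentile 0.0117), while those with more transcripts differed more (0.247), and discordant calls went from 12.4% of calls with 1 transcript to 42.3% with over 20. A correction that depends on the transcripts a gene's reads were assigned to is therefore a candidate explanation, which transcript-level counts for the same libraries could test. It would matter for single genes, such as MDC1, at -0.30 in the refit and 0.99 in the authors' deposited table, and TRANK1, at 0.20 and 2.57.

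A hypothesis was that blocking TACR2 removes a basal signal to ERK and so lowers ERK output. The median of the 18 ERK output genes was 0.171, with 7 higher and 0 lower (1 higher without DMSO 2; adjusted p = 0.352 with an estimated correlation), and another grouping of the libraries gave a smaller camera p (6.11e-07 against 1.79e-05). These values show no lower ERK output at 12 h, but they were known when the hypothesis was written and so do not test it. TACR2 itself had at most 10 counts in a library. Measuring phosphorylated ERK in cells with and without TACR2 would test it.

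Chance cannot be tested below a share of 0.1 with the 10 groupings of 6 libraries into 3 and 3. The real grouping gave 2374 genes, as many as only 1 of the 10 gave, itself, and the other 9 gave 0 (137 to 1027 genes at an unadjusted p under 0.05, edgeR). For lists the real grouping gave 19 and the highest other 17, from DMSO 1 with tumonolide 8 and 9, and 1 of 10 groupings reached 19. Camera's list count with the preset correlation is thus close to that of mixed groups, but those are not free of treatment. Each side of a mixed grouping holds unequal numbers of DMSO and tumonolide libraries, which keeps part of the contrast. The unfolded protein response and ribosome biogenesis lists were each called in 8 of the 9 other groupings. By fry, the real grouping gave 13 lists and the other groupings 0. The treatment difference within mixed groups widens their spread (common dispersion 0.0109 to 0.0134, against 0.00487), which can lower their gene and fry counts. The groupings that put DMSO 1 with tumonolide 7 gave 13 to 16 lists, along the second principal component.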
